A study of Mus musculus with 6 samples.

How the data were processed

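Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in 6 libraries of mouse embryonic stem cells, with 1 library for each combination of cell line and antibody. The cell lines were wild-type J1 cells (WT) and DNA methyltransferase triple-knockout cells (TKO), and the antibodies were anti-ATRX, anti-DAXX and non-specific rabbit IgG. Per the labels' protocols, cells were grown with the MEK inhibitor PD0325901 at 1 µM and the GSK3 inhibitor CHIR99021 at 3 µM, fixed in 4% paraformaldehyde for 10 min, and about 10 ng of precipitated DNA went into each library. Groups were taken from the sample titles.

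For each library 1 deposited list of peaks was used here. Bowtie2, Picard and the mouse build mm9 are named per the submitters' processing notes, without versions or roles. The peaks carry MACS names in the ATRX and DAXX lists, and the IgG tables have the columns of a MACS peak table, per the file headers. The caller's version, its settings and the control library of each call are not given in the sources used here. The ATRX and DAXX files deposited by the authors give a position and a score per peak. No header names the scale of this score. It was read as 10 times the negative log10 of the caller's p-value, a reading inferred from its values and from the headers of the IgG tables. It is the authors' value throughout and depends on the depth and control of each call, so it was used to rank and filter peaks and not as a measure of change between lists. The IgG tables deposited by the authors also give a count of tags (reads) per peak, the peak length and summit, and a fold enrichment over the caller's background. The lowest score was 50.02 in the WT DAXX list, 60.1 and 60.02 in the WT and TKO IgG lists, and between 70 and 70.01 in the other 3 lists, so the authors' thresholds differed between libraries. None of the files used here gives a total read number, and reads were not analysed here, so the depth of the libraries is not known from them, and a peak that is missing from a list was not shown to be unbound.

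Start positions of the BED lists were changed to count from 1, as in the IgG tables, and all coordinates are in mm9. Overlap between lists meant at least 1 bp in common, computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. The counts were checked against bedtools 2.31.1, which gave another count in 0 of 30 ordered pairs of lists. The level expected without any relation was taken from 1000 shuffles with a fixed seed. In these, each peak of 1 list was placed at random on its own chromosome, between the lowest start and the highest end of any peak listed there. The two-sided p-value from the shuffles cannot go below 0.002, and p-values were adjusted over the 30 ordered pairs by the Benjamini-Hochberg method, which gives 0.0043 for the smallest. Such a p-value describes the positions in these lists, and it is no test between cell lines or antibodies. The shuffles ignore mappability and gaps of the assembly, so part of any excess over them is shared by all peak lists of this genome. Shares of peaks are given with exact (Clopper-Pearson) 95% binomial intervals from scipy 1.17.1. Ratios of list lengths carry an interval made the same way. All of these cover counting error over peaks only. With 1 library per group there is no replicate error, and no difference between groups was tested.

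The place along chromosomes 8 and 11 where the number of TKO DAXX relative to WT ATRX peaks changed most was found by scanning all splits between occupied bins of 5 Mb, with the chi-square statistic. Its permutation p-value came from 10000 random orders of the bins, which allows for the choice of the split, and was adjusted over the 2 chromosomes. On simulated bins of chromosome 8 with 1 ratio throughout, 4 of 100 simulations passed a p of 0.05, and with a ratio 4 times higher in the last 7 of 25 bins 98 of 100 passed.

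The overlap and shuffle procedure was tested on simulated data made to the sizes of the TKO ATRX and TKO DAXX lists, with 40 simulations per level. Planted overlaps of 2%, 5% and 20% were returned as 2.05%, 5.04% and 20.1% on average, and all 40 simulations of each level passed a p of 0.05. With no planted overlap, 1 of 40 simulations passed. The simulated peaks were placed by the same rule as the shuffles. This count therefore checks the procedure and does not give its false-positive rate for real lists, whose peaks are not placed evenly.

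Regions were named by a rule fixed before the data were examined. For each ATRX and DAXX list these were the 10 highest-scoring peaks without an overlapping IgG peak of either line. To them were added the 10 regions with the best mean rank called for both factors in TKO cells and in neither WT list, the regions called in all 4 lists, and the 3 highest IgG peaks per line. Alternatives fixed at the same time were the removal of IgG-overlapping peaks, the upper 50% of each list by score, equal list sizes of 570 peaks, merging within 1 kb, leaving out chromosome Y, an overlap of 50% of the peak and a distance of 1 kb. A common score of 70, removal of peaks identical in 2 lists, an exchange of those lists and a fixed length of 400 bp were added after the data were seen. The shares on chromosomes 8 and 11, the scan along them and the clusters of peaks were also chosen after the data were seen. The gene table at hand belongs to another build than the peaks, and no mm9 sequence or annotation was used here. Tandem repeats, repeat classes, gene annotation, distance to chromosome ends, CpG content and the gene lists that had been fixed were therefore not analysed here, and regions are named by coordinates alone.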

Results

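The 6 peak lists compare where ATRX and DAXX are found on chromatin in cells with and without the DNA methyltransferases. ATRX is a chromatin remodeller, and DAXX is the histone chaperone that works with it to deposit histone H3.3. The peak lists hold no measure of DNA methylation in either line. The series was set up to ask whether this pair of proteins acts at repetitive DNA once DNA methylation is lost. WT J1 embryonic stem cells were compared with TKO cells, which lack the DNA methyltransferases. Rabbit IgG precipitates from each line gave the background. Each group holds 1 library, so none of the differences between groups has a replicate check. Library depth is not given in the files used here. The peaks of the WT IgG list hold 19267 tags and those of the TKO IgG list hold 69180.

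Under the labels as given, the TKO lists were longer than the WT lists for each of the 3 antibodies. The ATRX lists held 1440 peaks in WT and 1650 in TKO cells, a ratio of 1.15 (95% interval 1.07 to 1.23). The DAXX lists held 570 and 2046 peaks, a ratio of 3.59 (3.27 to 3.95). The IgG background moved the same way, from 402 to 1057 peaks, a ratio of 2.63 (2.34 to 2.96). Median peak length was 325 bp for WT ATRX, 348 bp for TKO ATRX and 328 bp for TKO DAXX, against 553.5 bp for WT DAXX. The WT DAXX list also ran down to a lower score than the others, and at a common score of 70 it held 299 peaks, which put the DAXX ratio at 6.84. That cut removed 0 TKO DAXX peaks, so it could only raise the ratio. At a score of 200 or more the order was the opposite, with 89 WT DAXX and 39 TKO DAXX peaks. The ATRX lists then held 8 WT and 36 TKO peaks, and the IgG lists 25 and 90. The direction of the DAXX difference thus depended on the score cut.

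The lists labelled WT ATRX and TKO DAXX were not independent of each other. They shared 750 peaks with the same start and the same end to the base, which was 52.1% of the WT ATRX peaks (49.5 to 54.7) and 36.7% of the TKO DAXX peaks (34.6 to 38.8). There were 0 overlaps between these lists that were not identical at both ends. The other 14 pairs of lists held 0 identical peaks. Of the 750 peaks, 105 had the same score in both lists, 348 scored higher in TKO DAXX and 297 scored lower, with a median difference of 0. For the 150 of them on chromosomes 8 and 11 the median difference, TKO DAXX minus WT ATRX, was 7.60, and for the others it was 0. Scores depend on the depth and control of each call, so these differences show no change in binding. The identical peaks were more frequent at high scores. They made up 70.8% of the 360 highest-scoring WT ATRX peaks (65.8 to 75.5) and 40.8% of the 360 lowest-scoring ones (35.7 to 46.1). Both lists stop at a score of 70.01, and a peak far above it in 1 list is more likely to pass it in the other. Such a rise can therefore come from the cut alone. The lists are named by their labels throughout, and which label fits the peaks could not be told from the lists, so every direction drawn from either depends on the labels. Without the 750 identical peaks the ratio of list lengths was 2.39 for ATRX (690 WT peaks) and 2.27 for DAXX (1296 TKO peaks). Their removal shortens 1 list of each ratio, so the rise of the first and the fall of the second follow by construction. With the WT ATRX and TKO DAXX lists exchanged, the ratio was 0.806 for ATRX (0.755 to 0.861), the opposite direction, and 2.53 for DAXX (2.29 to 2.79). The exchange describes a swap of the 2 labels. It does not cover 1 set of reads behind both lists, which would leave at least 1 group without its own list.

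**Figure D1:**
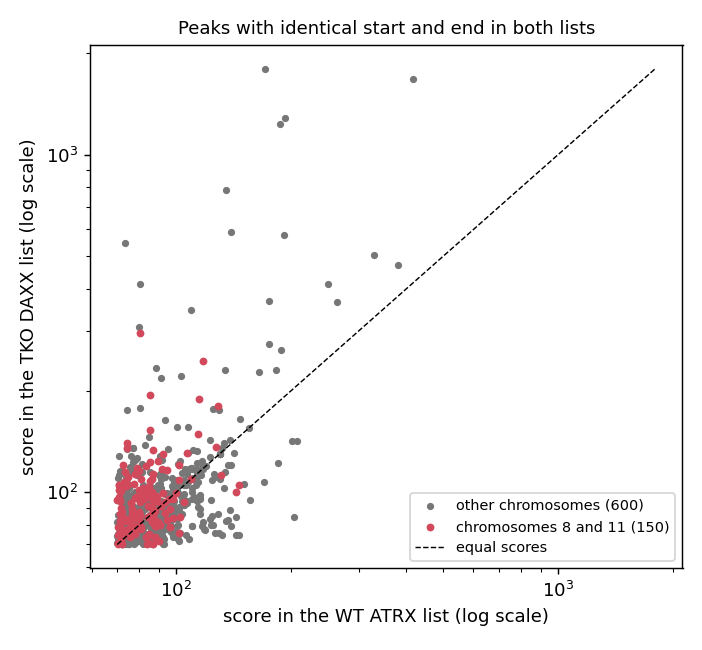
Each point is 1 of the 750 peaks with identical start and end in the WT ATRX and TKO DAXX lists, with its score in the WT ATRX list on the x axis and in the TKO DAXX list on the y axis (both log scales, 10 times the negative log10 of the caller's p-value, as read here). The 150 peaks on chromosomes 8 and 11 are in red, the dashed line marks equal scores, and the 10 highest TKO DAXX scores lie above it.

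Co-occupancy of ATRX and DAXX was compared within each cell line, under the labels as given. If 1 set of reads lies behind the WT ATRX and TKO DAXX lists, at least 1 line's share does not describe its 2 factors. Which line that would be cannot be told from the lists. In WT cells 33 of 1440 ATRX peaks overlapped a DAXX peak (2.29%, 1.58 to 3.20), and 32 of 570 DAXX peaks overlapped an ATRX peak (5.61%, 3.87 to 7.83). In TKO cells 107 of 1650 ATRX peaks overlapped a DAXX peak (6.48%, 5.34 to 7.78), and 112 of 2046 DAXX peaks overlapped an ATRX peak (5.47%, 4.53 to 6.55). Shuffled ATRX peaks met DAXX peaks 0.338 times on average in WT and 1.14 times in TKO cells, so the observed overlap was 97.6 and 93.5 times the shuffled one (adjusted p = 0.0043 for each, permutation of positions). The difference between the lines was not tested, and its size depended on which peaks entered. With the 570 highest-scoring peaks of each list the share of ATRX peaks was 4.39% in WT (2.86 to 6.41) and 9.65% in TKO cells (7.35 to 12.4), and in the upper 50% of each list it was 1.25% (0.573 to 2.36) and 9.09% (7.22 to 11.3). At a common score of 70 the WT share was 0.903% (0.482 to 1.54). Without the identical peaks the share was 3.48% in WT (2.24 to 5.13) and 3.70% in TKO cells (2.84 to 4.72). This removal shortens the DAXX list in TKO cells, so the TKO share could only fall by construction, while in WT cells it shortens the ATRX list itself. The share of DAXX peaks overlapping an ATRX peak was then 4.21% in WT (2.72 to 6.20) and 5.09% in TKO cells (3.96 to 6.43). With the WT ATRX and TKO DAXX lists exchanged the share of ATRX peaks was 0.489% in WT (0.235 to 0.897) and 3.27% in TKO cells (2.47 to 4.25).

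The same antibody was then compared between lines, under the labels as given. With 1 set of reads behind the WT ATRX and TKO DAXX lists, at least 1 of these comparisons would not be of 1 antibody. For ATRX, 55 of 1440 WT peaks overlapped a TKO peak (3.82%, 2.89 to 4.94), 73.4 times the shuffled number. For DAXX, 10 of 570 WT peaks overlapped a TKO peak (1.75%, 0.844 to 3.20), 17.7 times the shuffled number. Both passed the permutation of positions (adjusted p = 0.0043). WT DAXX peaks overlapped the TKO ATRX list in 14 of 570 cases (2.46%, 1.35 to 4.09). The ATRX peaks common to both lines lay mostly among the identical peaks, which held 46 of the 55, and the overlap was 1.30% (0.598 to 2.46) without them. Of the 10 DAXX peaks in common, 9 were identical peaks. The 1 that was left made 0.175% of the WT list, with an unadjusted permutation p of 0.6314, so the overlap no longer passed the test. With the lists exchanged, 5.61% of WT DAXX peaks (3.87 to 7.83) overlapped the DAXX peaks of TKO cells.

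**Figure D2:**
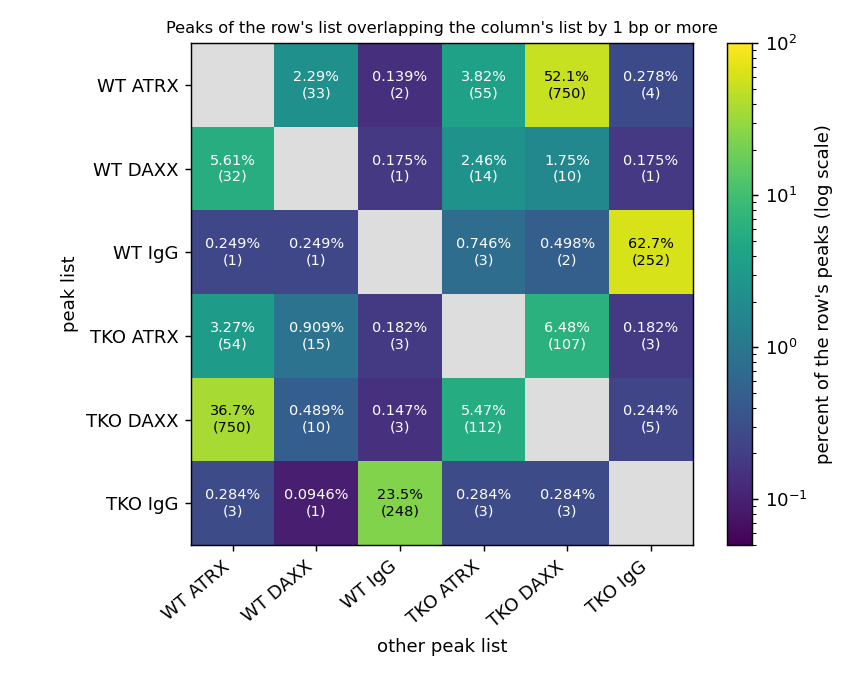
Each cell gives the percentage of the row list's peaks that overlap the column list by at least 1 bp (colour on a log scale), with the number of peaks in brackets. The pair WT ATRX and TKO DAXX (750 peaks) and the IgG pair (252 of 402 WT peaks) stand above the other pairs, which reach at most 6.48%.

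The top-ranked peak of the list labelled WT ATRX lay on chromosome 9 from 2,999,985 to 3,001,853 (score 416.54). It was followed by chromosome 7 from 87,938,261 to 87,939,949 (381.03), chromosome 3 from 154,135,877 to 154,137,115 (328.6) and chromosome 18 from 24,829,925 to 24,831,964 (263.8). Next came chromosome 2 from 130,034,062 to 130,035,439 (250.11) and chromosome 12 from 77,312,886 to 77,313,326 (206.47). The last 4 were chromosome 7 from 7,230,690 to 7,231,061 (202.76), chromosome 1 from 184,430,927 to 184,431,383 (200.72), chromosome 2 from 98,502,369 to 98,503,165 (192.11) and chromosome 9 from 3,019,582 to 3,020,648 (191.56). All 10 were identical in the TKO DAXX list, 6 overlapped a TKO ATRX peak and 2 overlapped a WT DAXX peak.

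Of the 10 top-ranked peaks of the list labelled TKO DAXX, 5 were also among the top 10 of WT ATRX. The list was led by chromosome 2 from 98,506,375 to 98,507,509 (score 1792.48) and from 98,502,369 to 98,503,165 (1286.1), and by chromosome 9 from 2,999,985 to 3,001,853 (1671.01) and from 3,023,282 to 3,025,215 (1228.02). A peak on chromosome 9 from 35,112,779 to 35,113,198 scored 785.25. The other 5 were chromosome 9 from 3,025,356 to 3,026,052 (588.49), from 3,019,582 to 3,020,648 (578.12) and from 3,034,573 to 3,036,398 (545.63), the chromosome 3 site (502.74) and the chromosome 7 site at 87,938,261 (469.75). All 10 were identical peaks of the WT ATRX list, 8 overlapped a TKO ATRX peak and 0 overlapped a WT DAXX peak.

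The TKO ATRX list was led by the chromosome 18 site, here from 24,830,047 to 24,831,980, with a score of 1152.59. Next were chromosome 12 from 4,536,927 to 4,538,028 (685.7), chromosome 1 from 184,430,854 to 184,431,549 (678.73), chromosome 5 from 33,015,214 to 33,016,169 (532.5) and chromosome 13 from 59,240,260 to 59,241,328 (510.11). Chromosome 1 from 194,495,777 to 194,497,547 scored 499.66, chromosome 9 from 123,842,850 to 123,843,827 scored 482.03, and chromosome 9 from 71,529,914 to 71,530,669 scored 467.26. The last were a 5860 bp interval on chromosome 17 from 39,979,926 to 39,985,785 (465.08) and chromosome 18 from 75,759,349 to 75,760,059 (448.95). Of these 10, 9 overlapped a TKO DAXX peak, 6 a WT ATRX peak and 4 a WT DAXX peak. The site on chromosome 13 was in no other list.

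The WT DAXX list had a different top. Its 10 highest peaks scored between 629.72 and 1007.39 and overlapped 0 peaks of any other list. They lay on chromosome 5 from 123,097,695 to 123,098,458 (1007.39), chromosome 6 from 108,135,188 to 108,135,991 (884.23), chromosome 4 from 126,754,169 to 126,754,864 (876.24) and chromosome 2 from 25,211,458 to 25,212,206 (776.29). Chromosome 9 held 2 of them, from 44,169,353 to 44,170,061 (736.54) and from 21,171,495 to 21,172,573 (721.17). The rest were chromosome 1 from 75,138,878 to 75,139,663 (673.52), chromosome 15 from 97,199,487 to 97,200,024 (648.81), chromosome 10 from 126,500,107 to 126,500,810 (636.01) and chromosome 8 from 3,500,031 to 3,500,747 (629.72).

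Joined over the 4 ATRX and DAXX lists, the peaks made 4795 regions, of which 51 were in at least 3 lists and 6 in all 4. The 6 were on chromosome 18 from 75,759,239 to 75,760,092, chromosome 9 from 123,842,850 to 123,844,940, chromosome 1 from 184,430,835 to 184,431,549, chromosome 5 from 33,014,588 to 33,016,170, chromosome 18 from 73,607,326 to 73,607,746 and chromosome 2 from 26,502,151 to 26,502,861. The first of them scored 174.58 for WT ATRX, 126.62 for WT DAXX, 448.95 for TKO ATRX and 274.26 for TKO DAXX. All 6 held a peak that is identical in the WT ATRX and TKO DAXX lists. That follows largely by construction, since these 2 lists had no overlap that was not identical. They do not count as independent calls of a region.

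Regions called for both factors in TKO cells numbered 106, and 60 of these were in neither WT list. The best-ranked of the 60 was on chromosome 6 from 142,698,787 to 142,699,997, with scores of 411.15 for ATRX and 245.28 for DAXX. It was followed by chromosome 5 from 100,779,632 to 100,780,633 (179.1 and 238.07), the long interval on chromosome 17 (465.08 and 143.45) and chromosome 12 from 4,536,927 to 4,538,037 (685.7 and 138.8). The next were chromosome 9 from 121,606,751 to 121,607,206 (206.15 and 160.95), chromosome 12 from 70,712,072 to 70,712,791 (151.33 and 180.22) and chromosome 11 from 119,975,492 to 119,976,341 (151.48 and 154.3). The last 3 were chromosome 12 from 3,235,625 to 3,236,210, chromosome 2 from 152,727,103 to 152,727,815 and chromosome 8 from 123,990,088 to 123,991,187. Their ATRX scores were 142.69, 143.58 and 204.43. In WT cells 32 regions were called for both factors. These numbers depend on the labels of the WT ATRX and TKO DAXX lists.

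The IgG background fell mostly elsewhere in the genome. In the WT IgG list 252 of 402 peaks overlapped a TKO IgG peak (62.7%, 57.8 to 67.4; adjusted p = 0.0043, permutation of positions). Chromosomes 4, 14 and 17 held 34.6% of the WT and 44.1% of the TKO IgG peaks, against 10.6% to 17.4% of the ATRX and DAXX peaks. The highest WT IgG peaks were on chromosome 8 from 27,079,912 to 27,080,479 (score 1356), chromosome 15 from 91,737,399 to 91,738,742 (912.3) and chromosome 8 from 15,519,775 to 15,520,123 (605.82). The TKO list was led by chromosome 15 from 91,738,846 to 91,740,326 (1533.59) and from 91,737,378 to 91,738,787 (1340.71), and by chromosome 8 from 27,079,862 to 27,080,611 (1178.92). The median fold enrichment given by the authors was 70.9 in WT and 28.5 in TKO IgG peaks. Few antibody peaks met IgG peaks of their own line. The numbers were 2 for WT ATRX (adjusted p = 0.0569), 1 for WT DAXX (0.2509), 3 for TKO ATRX (0.099) and 5 for TKO DAXX (0.0133), by permutation of positions. Each lay above the mean of the shuffles, which was 0.203, 0.121, 0.727 and 0.841 in that order, and only TKO DAXX passed. The control of each call is not given, so these low numbers do not show that the antibody peaks are free of background.

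Chromosomes 8 and 11 carried a larger share of the peaks in the list labelled TKO DAXX than in the other 5 lists. Chromosome 11 held 402 of them (19.6%) and chromosome 8 held 253 (12.4%), together 32.0% (30.0 to 34.1). The same chromosomes held 17.1% of the WT ATRX peaks (15.2 to 19.13), 13.9% of the WT DAXX peaks (11.1 to 17), 12.1% of the TKO ATRX peaks (10.5 to 13.7) and 8.14% of the TKO IgG peaks (6.56 to 9.95). The number of TKO DAXX peaks relative to WT ATRX peaks was 3 on chromosome 11 and 2.26 on chromosome 8, and between 0.784 and 1.75 on the other 18 chromosomes compared. On chromosome 8 the excess lay in the distal part. From 95 Mb on there were 173 TKO DAXX and 41 WT ATRX peaks, a ratio of 4.22 (2.99 to 6.09), and before it 80 and 71, a ratio of 1.13 (0.808 to 1.57; adjusted p = 0.0034, permutation of bins). On chromosome 11 the ratio was 2.51 (1.90 to 3.34) before 75 Mb and 3.59 (2.69 to 4.85) from there on, which did not pass the same permutation test (adjusted p = 0.5594). The intervals of these ratios treat the 2 lists as independent, though they share peaks, and do not allow for the choice of the split. The share on both chromosomes was 39.0% (36.3 to 41.7) among the 1296 TKO DAXX peaks outside the identical set and 20% (17.2 to 23.0) within it. In the WT DAXX list chromosome 13 held as many peaks as chromosome 11, 52 each (9.12%).

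**Figure D3:**
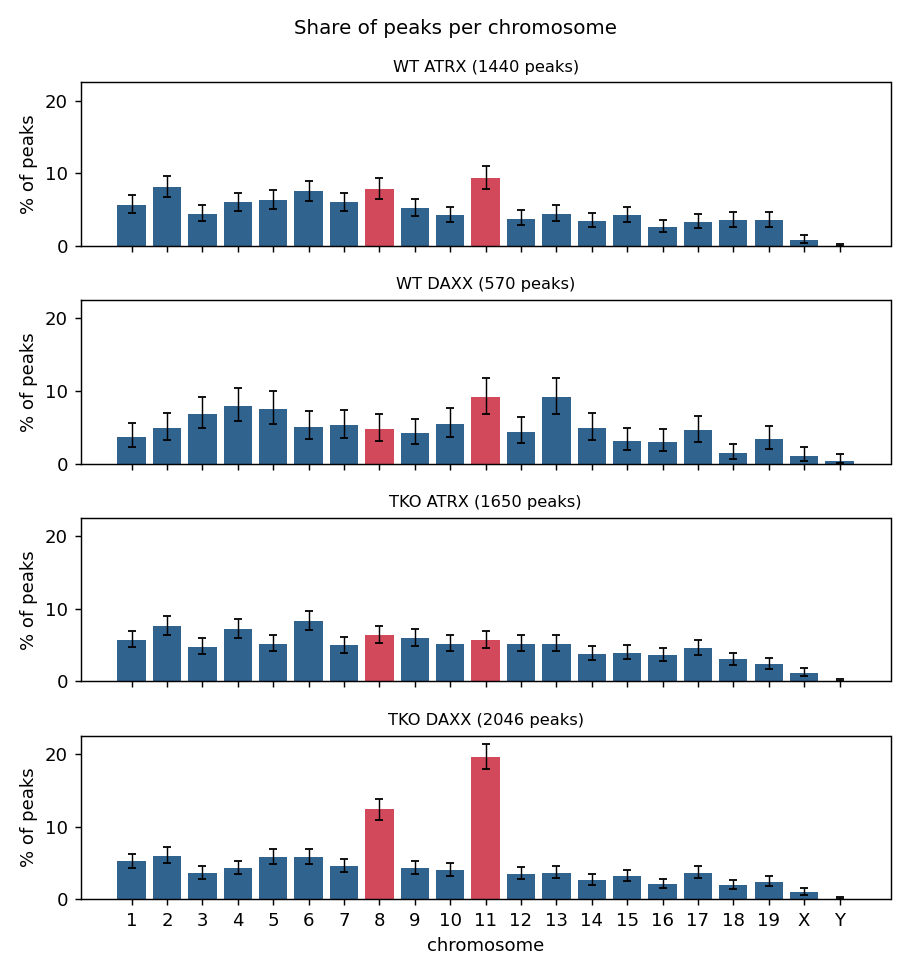
Bars give the percentage of each list's peaks on each chromosome for the 4 ATRX and DAXX lists, with exact 95% binomial intervals, and chromosomes 8 and 11 are in red. In the TKO DAXX list these hold 12.4% and 19.6% of the peaks.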

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

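A common score of 70, removal of the identical peaks, an exchange of the WT ATRX and TKO DAXX lists and a fixed length of 400 bp were chosen after the data were seen. Of 221 recomputed values, 189 were counted as unchanged, among them 145 of the 158 recomputed overlaps. An overlap was so counted if it stayed on its side of the threshold, judged here by unadjusted p, whatever its size. A passing overlap also had to keep its direction. The TKO ATRX overlap with IgG, which had not passed, was thus counted as unchanged where it fell to 0. List lengths were so counted within a factor of 1.5, which includes the exchange of 1440 and 2046 peaks. Overlaps under exchanged lists are those of other pairs under new names. Of the 189, 14 could not have changed, because the setting left their lists as they were or shortened both alike. Of the rest, 18 moved, 6 no longer passed, 3 newly passed and 5 reversed. Taking the upper 50% by score set the list lengths by construction to 720 (WT ATRX), 285 (WT DAXX), 201 (WT IgG), 825 (TKO ATRX), 1023 (TKO DAXX) and 529 (TKO IgG). The WT ATRX share on chromosomes 8 and 11 was then 15%, which does not follow by construction. A common score of 70 left 299 WT DAXX peaks and a DAXX ratio of 6.84, by construction, since the WT DAXX list alone of the 4 antibody lists ran below it. Removing the identical peaks left 690 WT ATRX and 1296 TKO DAXX peaks, ratios of 2.39 (ATRX) and 2.27 (DAXX), and shares on chromosomes 8 and 11 of 13.9% (WT ATRX) and 39.0% (TKO DAXX). The change of both ratios follows by construction. Removal ended the overlap of the DAXX lists between lines, 0.175% of WT and 0.0772% of TKO peaks, and by construction took the overlap of WT ATRX with TKO DAXX to 0. Exchanging the lists turned the ATRX ratio to 0.806, took the DAXX ratio to 2.53 and, by construction, swapped their shares on chromosomes 8 and 11 (32.0% for WT ATRX, 17.1% for TKO DAXX). The share of ATRX peaks in DAXX peaks passed in all settings but ranged from 0.489% to 4.39% in WT and from 3.27% to 9.65% in TKO cells. The overlaps with IgG rest on 1 to 5 peaks and moved across the threshold easily. For WT ATRX the share was 0 in the upper 50%, at equal list sizes and without the identical peaks, 0.0700% after merging and 0.139% with a distance of 1 kb, where it no longer passed. For TKO DAXX it no longer passed at equal list sizes (0.175%) or after merging (0.150%). For TKO ATRX, which had not passed at first, the share was 0 in the upper 50% and at equal list sizes. It passed with an overlap of 50% (0.182%), at the common score (0.182%) and with a distance of 1 kb (0.424%). Apart from those that follow by construction, the cause was not tested. Removal of IgG-overlapping peaks gave no value for the IgG overlaps themselves. Alternatives for tandem repeats, repeat classes, annotation, chromosome ends, CpG content and gene lists were not run, for lack of a genome of the files' build. No paired analysis was possible because each group holds 1 library. Depth, which the files used here do not give, limits each statement that a site was in 1 list and not in another.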

Other observations

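The tests on the identical peaks, on chromosomes 8 and 11, on clusters and on the DAXX ratio were chosen after the patterns they bear on had been seen; for the count of 1 peak per Mb and the overlap with ATRX on chromosomes 8 and 11, what each explanation would give was set out before the value of the test was seen.

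Peaks of a list lying within 50 kb of each other in groups of 5 or more formed 6 clusters in the WT DAXX list, which held 8.25% of its peaks (6.12 to 10.8). Of these, 4 lay on chromosome 13, with 12 peaks from 23,492,475 to 23,618,696, 8 from 21,252,479 to 21,415,008, 8 from 21,974,654 to 22,067,076 and 5 from 23,362,107 to 23,409,628. Another held 9 peaks on chromosome 3 from 96,125,688 to 96,232,344, and the last 5 peaks on chromosome 11 from 68,849,922 to 68,887,484. The other lists placed 0 peaks inside 5 of the 6 clusters, and 1 TKO ATRX peak lay inside the interval from 21,974,654. Mouse chromosomes 13 and 3 are known to carry clusters of histone and transfer RNA genes. Whether these peaks lie in them was not examined, since no annotation of the build was used.

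The start of chromosome 9, from 2,999,985 to 3,038,280, held 27 TKO DAXX peaks and 11 WT ATRX peaks, all 11 of them identical in both lists. It held 5 TKO ATRX, 0 WT DAXX, 1 WT IgG and 0 TKO IgG peaks. At the far end of the X chromosome 7 TKO DAXX peaks lay between 166,578,438 and 166,614,156, where the TKO IgG list had 2 peaks, the WT ATRX list 1 and the TKO ATRX list 0. Above 166 Mb on X the WT and TKO IgG lists held 4 and 9 peaks in all. On chromosome 8 from 125,949,701 to 125,958,443 the TKO DAXX list had 7 peaks, the WT ATRX list 1 and the other 4 lists 0. On chromosome 10 from 84,600,450 to 84,706,417 only the TKO ATRX list of the 6 had peaks, 5 in number. IgG peaks were clustered far more, with 53.5% of the TKO and 33.1% of the WT IgG peaks in such groups.

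The 750 identical peaks are the first pattern to look at again. Of the overlapping WT ATRX peaks, 100% were identical at both ends, which is consistent with 1 set of ChIP reads behind both lists, called against different controls, a reading that rests on how the caller is understood to set peak ends. Separate libraries bound at the same sites would give many overlaps with different ends, and 0 were found, while the TKO ATRX and TKO DAXX lists overlapped at 107 ATRX peaks with 0 identical. Coordinates written from a list of regions common to all libraries would give identical peaks in other pairs, and 0 were found in the other 14 pairs. This count cannot decide on a list made for this pair of libraries alone, which would also give 0 there. Which of the labels fits the reads remains open, and so does whether either list holds further reads of its own.

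For the second pattern, the 32.0% of TKO DAXX peaks on chromosomes 8 and 11, a candidate explanation is a difference in copy number or coverage between the ChIP cells and the control used for this list. Along the whole of chromosome 11 it would need an excess throughout. There the TKO DAXX list exceeded the WT ATRX list in 88% of 25 occupied 5 Mb bins (68.8 to 97.5), against 45.8% outside both chromosomes. Along the whole of chromosome 8 it is argued against by the ratio of 1.13 (0.808 to 1.57) before 95 Mb beside 4.22 (2.99 to 6.09) from there on. The intervals do not allow for the choice of this split, but the permutation of bins does (adjusted p = 0.0034). A difference in the distal part is left open. Counting 1 peak per Mb gave 16.4%, inside the WT ATRX interval (12.3 to 17), which met what had been set out for dense clusters, but at 3.97 peaks per occupied Mb against 1.88 the measure was judged saturated after this value was seen. Without clusters within 50 kb, a test then added, the share was 32.1% (30.0 to 34.2), which argues against clusters of that kind and leaves wider ones open. Sites shared with the TKO ATRX list are argued against as the source of the excess. Of the TKO DAXX peaks on these chromosomes 2.60% overlapped a TKO ATRX peak (1.52 to 4.12), and 6.83% of those elsewhere did (5.56 to 8.28). Binding of ATRX without a listed peak is left open, because a missing peak was not shown to be unbound. The label of the TKO DAXX list is open too.

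The third is the 3.59-fold longer DAXX list in TKO cells. The lower threshold of the WT list adds WT peaks and so lowers this ratio, by construction. A difference between the lines or libraries that also appears with IgG could contribute, as the IgG ratio was 2.63 (2.34 to 2.96). Under the labels as given the DAXX ratio lay above it. With the WT ATRX and TKO DAXX lists exchanged it was 2.53 (2.29 to 2.79), within the interval of the IgG ratio. That match holds at the authors' unequal thresholds and only for a swap of the 2 labels. If 1 set of ChIP reads lies behind both lists, the same reads stand for both groups in either order. The match then says nothing about the DAXX ratio. At a common score of 70 the exchanged lists held 299 WT and 1440 TKO DAXX peaks, a ratio above that of IgG, 2.76 (2.41 to 3.17). At a score of 200 or more the order was the opposite, with 89 WT and 39 TKO DAXX peaks (8 with the lists exchanged). Whether the DAXX ratio goes beyond that of IgG cannot be told, with the cut and that label open, 1 library per group and no depth given in the files used here. An effect of the lost DNA methyltransferases, the difference that the design names, stays open and untested, and 750 of the 2046 peaks are also those of the WT ATRX list.

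Within the WT ATRX list the 690 peaks outside the identical set overlapped WT DAXX peaks in 3.48% of cases (2.24 to 5.13) and TKO ATRX peaks in 1.30% (0.598 to 2.46). The 750 identical peaks did so in 1.20% (0.550 to 2.27) and 6.13% (4.53 to 8.10). The 1296 TKO DAXX peaks outside the identical set overlapped TKO ATRX peaks in 5.09% (3.96 to 6.43) and WT DAXX peaks in 0.0772% (0.00195 to 0.429). These differences were not tested.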
